A study of Mus musculus with 8 samples.

How the data were processed

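Chromatin immunoprecipitation with sequencing (ChIP-seq) of the transcription factor Pax6 was analysed in alphaTC1 cells, a mouse glucagon-producing pancreatic alpha-cell line. The cells had received antisense oligonucleotides with a scrambled control sequence (control knockdown, control KD) or oligonucleotides against Paupar (Paupar KD), a long non-coding RNA transcribed next to Pax6. The series has 8 libraries: 2 Pax6 ChIP and 2 input libraries in each group, which the series' design text describes as duplicate biological samples. The input libraries were not analysed here. Per the submitters' processing notes, the tools were Bowtie2, MACS2, DiffBind and ChIPseeker, without versions, and the genome build was mm10. The test inside DiffBind, the normalization between libraries and the use made of the input libraries are not given in the sources used here. The read depth of each library is unknown, so no counting interval was computed for any signal.

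A table of 26244 sites, each a window of 100 bp, held the authors' own comparison. Its concentrations and fold were read as log2 values, a scale that the column names do not state. The concentrations are the authors' mean over the libraries of each group, with no value per library. The authors' log2 fold was control KD minus Paupar KD; the sign was turned here, so that a positive log2 change is a higher signal after Paupar KD. The fold differed from the difference of the concentrations by over 0.01 at 0 sites. The authors' p-value and false discovery rate (FDR) were used as deposited, and no test of the sites was run here, because the table holds group means. The −log10 of the FDR is a further deposited column of the authors and was not needed. At 1010 sites, with mean concentrations up to 2.62, the deposited FDR was 1 although the p-value was below 0.99, so these sites lay outside the authors' adjustment; the other 25234 sites were the background of the enrichment tests. The alternatives by subset were tested against the sites of that subset, and the one at an unadjusted p below 0.05 against all 26244 sites. The lowest concentrations were -0.01 in control KD, at 522 sites, and -0.02 in Paupar KD; 24 sites lay at or below 0 in Paupar KD. Such sites are said to be listed at the floor, with both concentrations and no fold. Gene symbols are the authors' annotation to a nearest gene. A spreadsheet had turned 51 symbols of 13 genes into dates, and these were restored from the Entrez gene ID with a gene table of the GRCm38.p6 assembly; 99.97% of the sites had an ID in it.

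Each ChIP library also had a list of peak summits, called per library, as the single library name in each list shows. The list of control KD replicate 2 carries another replicate number than its title; it was assigned by the sample it was deposited under. The score of a summit is the authors' own value, read as −log10 of the q-value from its lowest value (2.0 to 2.01 in the deposited lists, a q of 0.01); it was used only to rank and filter summits within a list. Summits of the 4 libraries within 250 bp were chained into summit sites, and a library supported a site if it had at least 1 summit in it. A site of the table was matched to summits within 250 bp of its middle; 25314 sites had such a summit and 930 had none. Jaccard indices were computed for each pair of libraries, and the real grouping was set against the other splits of the 4 libraries into pairs, 3 splits in all, as an exact permutation test. Coordinates are 1-based, on mm10.

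Sites with an FDR below 0.05 were taken as called. Fisher's exact test (two-sided) compared the called sites of each annotation class, and of each of 13 gene lists, with the remaining background, with Benjamini-Hochberg adjustment over all classes and directions, and over the 26 list tests. Neighbouring sites are not independent replicates, so these tests describe the sites. Counts adjusted over a list alone applied Benjamini-Hochberg to the deposited p-values of all its sites, those outside the authors' adjustment included. Such counts were not set against random lists. Each list's median log2 change was ranked among 10000 random sets of sites of the same size, matched on mean concentration in 20 bins. The lists were alpha-cell identity, beta-cell identity, other islet hormones and delta-cell markers, islet transcription factors, hormone secretion and processing, islet receptors, the lens and eye Pax6 programme, the neural Pax6 programme, neighbours of the Pax6 locus, splicing factors, ribosomal protein genes, zinc finger genes and histone genes; some genes were in more than 1 list. Shares of calls carry exact (Clopper-Pearson) 95% intervals. Bootstrap intervals rest on 2000 resamples and the gene-level permutation on 100000. The list test was tested on simulated data over 25234 sites: for higher sites in a list of 200 sites it called 3.0% of 200 simulations with no enrichment and 98.5% with an odds ratio of 3, at an unadjusted p below 0.05. Most lists were smaller: with an odds ratio of 3 it called 39.0% at the 33 sites of the beta-cell list, 66.5% at the 69 of the alpha-cell list, 80.0% at the 94 of islet transcription factors and 9.5% at the 7 of other islet hormones and delta-cell markers. The simulated list sites were drawn at random and called independently, so these shares may not hold for lists with several sites per gene. The chaining recovered 5000 of 5000 planted shared sites and 4000 of 4000 private sites. The planted summits of a site lay within the linking distance, and the sites lay far apart, so this outcome was fixed by the setting. It does not cover sites whose summits lie further apart. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.

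The groups, tests, gene lists, most alternatives and the rule for named genes were fixed before the data were examined. The rule named the 10 called sites with the largest rise and the 10 with the largest fall, 1 per gene; the 10 sites with the highest mean signal; up to 4 genes per list, called sites first and then by mean signal; Gcg, Neurod1, Pcsk2, Pax6, Ins2 and further islet genes in every case; and up to 5 summit sites each way found in 1 group alone, by score. Further called members of the lists, the other sites of Gcg, Pax6 and Paupar, and genes with several called sites were added after their values were seen. Some genes that the rule names are not reported here. The alternatives tried were other FDR thresholds, a filter on low signal, centring, subsets of sites by annotation and by summit support, the strongest site per gene, other linking distances and score thresholds, equal list lengths, leaving out sites at the floor and leaving out each library. A split by the smaller of the control KD and Paupar KD concentrations was also run and dropped, because it removes sites that rose. Above its median, lower calls outnumbered higher calls. The planned search of summits for motifs was left out, because it needs a genome sequence, which was not used here.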

Results

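Pax6 binding was measured by ChIP-seq in alphaTC1 cells, a mouse pancreatic alpha-cell line, after control KD or Paupar KD, with 2 Pax6 ChIP libraries per group. Pax6 is a paired-domain and homeodomain transcription factor needed for islet endocrine cells, and Paupar is a long non-coding RNA transcribed next to it. The question was whether Pax6 occupancy of the genome differed after Paupar KD. The authors' deposited table listed 26244 sites annotated to 10197 genes, with mean log2 concentrations per group and no value per library. Of these sites, 27.5% were annotated to promoters, 36.8% to introns and 28.9% to distal intergenic sequence. The read depth of the libraries was not given in the sources used here, and the level of Paupar RNA was not measured by this assay.

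Among the always-named alpha-cell genes, Gcg, which encodes the glucagon precursor, had 3 of its 5 sites higher after Paupar KD in the authors' deposited table. A site 1.43 kb upstream of a Gcg start (chromosome 2, 62485081 to 62485180, mm10) went from a concentration of 2.53 to 6.90, a log2 change of 4.36 (FDR 0.0317), in the authors' deposited table. The authors' own test gave p = 0.00101 there, but p = 4.01e-11 at a Ptprt site of similar mean signal and smaller change (3.71 and 6.69). Whether libraries of a group differed more at the Gcg site cannot be seen without values per library. A second site (62478621 to 62478720), inside the Gcg gene, had 1.55 in control KD and 4.72 in Paupar KD (FDR 0.0200) in the authors' deposited table. Another site in the gene (62480465 to 62480564) was listed at the floor in control KD (-0.01) and at 4.69 in Paupar KD (FDR 0.0102) in the authors' deposited table. The strongest Gcg site, at the promoter (62483607 to 62483706), had concentrations of 7.01 and 7.64 and an FDR of 0.155 in the authors' deposited table. The fifth, downstream of the gene, had 3.38 and 4.43 (FDR 0.551) in the authors' deposited table. Of the 3 higher Gcg sites, none had a summit in a control KD library, and the site at 62478621 had one in Paupar KD replicate 1 alone.

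**Figure D1:**
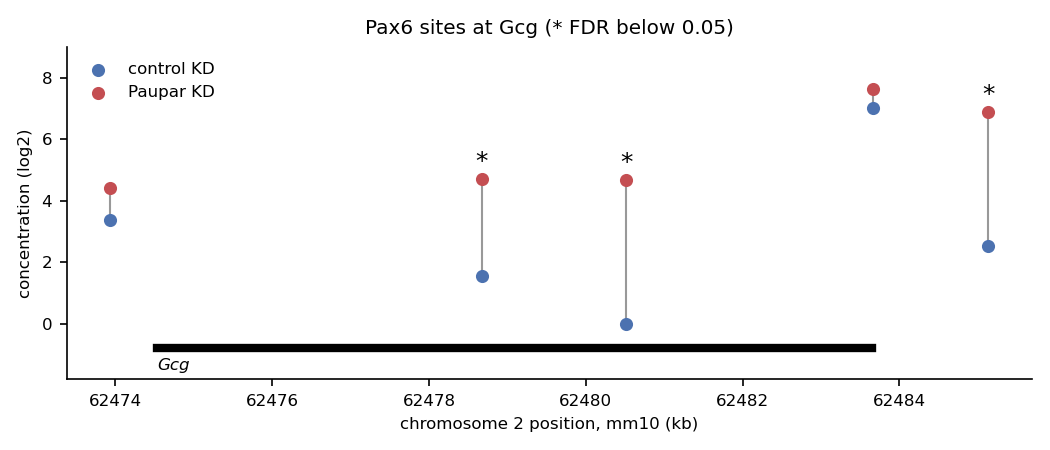
Mean log2 concentration of the 5 Gcg sites in the authors' deposited table (vertical axis) against the position on chromosome 2 in kb, mm10 (horizontal axis), for control KD (blue) and Paupar KD (red); the black bar is the span of Gcg in the GRCm38.p6 gene table, and no error is drawn because the table gives group means. The 3 sites with a star had an FDR below 0.05, and the promoter site went from 7.01 to 7.64 with an FDR of 0.155.

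The strongest site of Neurod1, an islet basic helix-loop-helix factor gene, lay at its promoter (FDR 0.580) in the authors' deposited table. The only listed site of Pcsk2, which encodes the convertase that releases glucagon, also lay at its promoter (FDR 0.476) in the authors' deposited table. No site of Ins2 was listed. At Pax6 itself 0 of 9 sites passed an FDR of 0.05, and the strongest (105674692 to 105674791) had 7.52 and 7.23 (FDR 0.643) in the authors' deposited table. The site at the Paupar promoter (105661909 to 105662008) had 8.20 and 7.78 (FDR 0.351) in the authors' deposited table. A higher site assigned to Paupar, 109 kb from its start in an intron of the antisense transcript Pax6os1 (105552302 to 105552401), had 0.61 and 4.81 (FDR 0.00736), with a summit in Paupar KD replicate 1 alone, in the authors' deposited table.

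By lists fixed beforehand, beta-cell identity genes were the 1 list whose higher sites passed the test. Of its 33 background sites, 6 were higher and 0 lower after Paupar KD (odds ratio 6.37, Fisher's exact p = 0.000752, adjusted p = 0.0196). Adjusted over the list alone, with 35 sites in all, 11 were higher. Among the 6 sites called higher were those at G6pc2, an islet glucose-6-phosphatase gene, and Slc30a8, which encodes the zinc transporter of insulin granules. The others were at Npy, Iapp, which encodes amylin, and Nkx6-1, a beta-cell homeodomain factor gene. The G6pc2 promoter (chromosome 2, 69219901 to 69220000) went from 2.34 to 5.54 (FDR 0.000452) in the authors' deposited table. The site assigned to Iapp, 8.78 kb upstream (chromosome 6, 142289548 to 142289647), went from 3.69 to 7.21 (FDR 0.00903) in the authors' deposited table. The authors' own test gave p = 0.000139 there, also larger than at the Ptprt site named above, although the change was larger. Slc30a8 had 2 higher sites, the promoter (5.80 and 6.89, FDR 0.0397) and a distal site (4.23 and 6.15, FDR 0.00284), in the authors' deposited table. Npy had 5.91 and 7.15 at a site 166 kb upstream (FDR 0.00548), and Nkx6-1 was listed at the floor in control KD and at 4.36 in Paupar KD at a site 140 kb away with a summit in Paupar KD replicate 1 alone (FDR 0.0285), in the authors' deposited table. The list's median log2 change was 0.36, at the 99.5 percentile of matched random sets. Without sites at the floor, whose folds are no measure of size, it was 0.205 (98.5 percentile).

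Alpha-cell identity genes had 7 higher and 0 lower of 69 sites, with Gcg, Etv1 and Irx1 among their genes (odds ratio 3.24, Fisher's exact p = 0.00873, adjusted p = 0.114), which did not pass the adjustment. Adjusted over the list alone, 9 sites were higher and 0 lower. Uncalled sites 10 kb to 1 Mb from the higher sites of both identity lists had a median log2 change 0.29 above that of sites of matched mean signal (95% bootstrap interval 0.04 to 0.42). Islet transcription factor genes had 7 higher and 0 lower of 94 sites (odds ratio 2.31, Fisher's exact p = 0.0405, adjusted p = 0.351; 12 higher and 1 lower adjusted over the list alone), and their median of -0.035 had the opposite sign. Matched random sets had a median of -0.135, and the list lay at their 87.6 percentile. Their called sites included Rfx3 (2.07 and 5.91, FDR 1.7e-05), the promoter of St18 (4.75 and 6.74, FDR 5.99e-05), Sox4 (4.15 and 5.69, FDR 0.0472) and Etv1 (5.39 and 6.67, FDR 0.0198) in the authors' deposited table. Hormone secretion and processing genes had 6 higher and 1 lower of 162 sites (odds ratio 1.10, Fisher's exact p = 0.825 for higher sites, adjusted p = 1.0; 6 higher and 1 lower adjusted over the list alone). These included Cpe, which encodes carboxypeptidase E (5.11 and 7.25, FDR 4.43e-06), Pam (4.71 and 6.83, FDR 0.000198), Snap25, Scn3a and Ptprn, and the lower site of Unc13a (7.48 and 6.63, FDR 0.0456), in the authors' deposited table.

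Islet receptor genes had 3 higher and 0 lower of 38 sites (Fisher's exact test, adjusted p = 0.771; 4 higher and 1 lower adjusted over the list alone), at Gria2, Gpr119 and Adra2a. Splicing factor genes had 3 higher and 0 lower of 43 sites (Fisher's exact test, adjusted p = 0.771; 5 higher and 0 lower adjusted over the list alone), at Mbnl1, Mbnl2 and Srsf6. The neural Pax6 programme had 2 higher and 0 lower of 28 sites (Fisher's exact test, adjusted p = 0.801; 3 higher and 0 lower adjusted over the list alone), at the Notch effector gene Hes1 and at Meis1. The lens and eye programme had 1 higher and 0 lower of 32 sites (Fisher's exact test, adjusted p = 1.0; 1 higher and 0 lower adjusted over the list alone), at Maf. Neighbours of the Pax6 locus had 1 higher and 0 lower of 18 sites (Fisher's exact test, adjusted p = 1.0; 1 higher and 0 lower adjusted over the list alone). Ribosomal protein genes had 1 higher site, at Rps4l, and 2 lower sites, at Rps28 and Rps24, of 79 (Fisher's exact test, adjusted p = 1.0 and 0.771; 1 higher and 2 lower adjusted over the list alone). Zinc finger genes had 8 higher and 5 lower of 355 sites (Fisher's exact test, adjusted p = 0.864 and 0.801; 6 higher and 5 lower adjusted over the list alone), with lower sites at the promoters of Zfp651 (9.29 and 8.42, FDR 0.000777), Zfp384 (7.34 and 5.99, FDR 0.00939) and Zfp422 (7.50 and 6.53, FDR 0.0228) in the authors' deposited table. Histone genes, with 36 sites, and other islet hormones and delta-cell markers, with 7, had 0 called sites; adjusted over the list alone, the histone genes had 0 and the islet hormone list 2 higher and 0 lower. Hhex, a delta-cell factor gene of that list, had 5.98 and 6.87 (FDR 0.101) in the authors' deposited table.

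Over all genes, 855 sites at 753 genes were higher and 222 sites at 217 genes lower after Paupar KD at an FDR below 0.05 in the authors' deposited table, so that 79.4% of calls were higher (95% interval 76.9 to 81.8%). The higher sites had a median concentration of 2.20 in control KD and 5.29 in Paupar KD in the authors' deposited table, and 119 of them were listed at the floor in control KD. The lower sites were stronger, with medians of 7.22 and 6.18 and a median log2 change of -1.08, in the authors' deposited table. The rule for the largest rises named 10 genes, and the floor value in control KD set the order of 9 of them and their place above other genes. Listed at the floor were Lpp and Maf (5.89 each in Paupar KD), Dapk1 (5.61), 4930556N09Rik (5.45), Nobox (5.34), Hepacam2 (5.31), Gm10400 (5.30), 5033404E19Rik (5.27) and Klf4 (5.27), in the authors' deposited table. Of these, Dapk1, 4930556N09Rik, Nobox, Gm10400 and Klf4 had a summit in Paupar KD replicate 1 alone. C6, a complement component gene, had 1.04 and 6.37 at an exon site (log2 change 5.32, FDR 2.27e-07) in the authors' deposited table. That control KD value lay near the floor, so the size of this change is uncertain as well. The largest falls were at Tbc1d22a (log2 change -2.85, FDR 0.0160), Col5a1, a collagen gene (-2.78, FDR 0.0459), and Mtx2 (-2.54, FDR 0.0367) in the authors' deposited table. Olfm2 (-2.39), Pcnx2 (-2.30), Sh3kbp1 (-2.22), 1700012D14Rik (-2.18), Lipc, the hepatic lipase gene (-2.17), Tbc1d30 (-2.11) and Dpf3 (-2.08) followed, with FDRs of 0.0233 to 0.0495, in the authors' deposited table. Among these falls, 1700012D14Rik and Tbc1d30 had summits in both control KD libraries, and each other site in a single control KD library. The 10 sites with the highest mean signal were assigned to Plekha1, Pisd-ps3, Wipi2, BC003965, Zfp648, Tmem51os1, Cherp, Pde1c, Chchd5 and Map3k21; Wipi2 (10.01 and 9.34, FDR 0.0122) and Tmem51os1 (9.80 and 8.89, FDR 0.00799) were lower in the authors' deposited table. In the highest quartile of mean signal 77.1% of sites had a log2 change below 0, so direction did not set these calls apart.

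**Figure D2:**
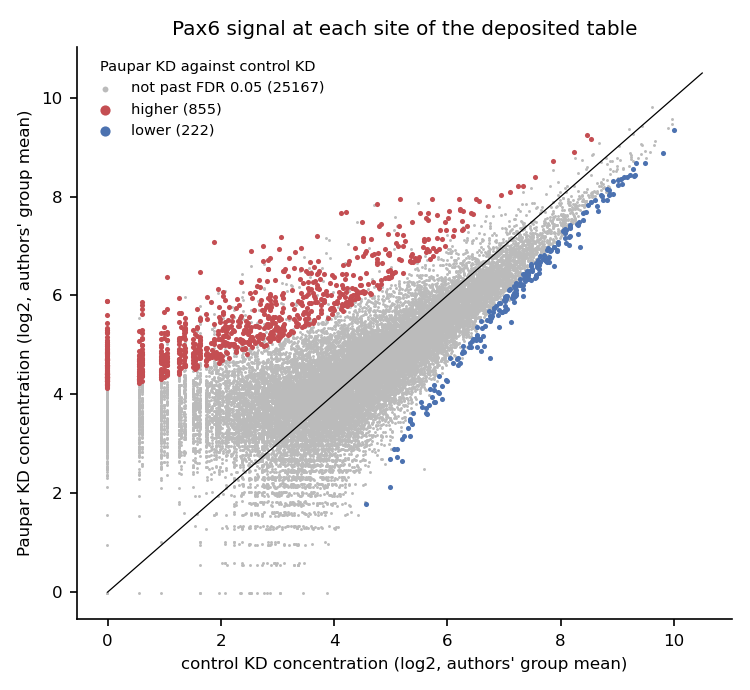
Mean log2 concentration of each of the 26244 sites in control KD (horizontal axis) and Paupar KD (vertical axis) in the authors' deposited table, with the line of equal values; red points are the 855 higher sites, blue points the 222 lower sites and grey points the rest. The column of points at the left edge holds the sites listed at the floor in control KD.

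The direction of the calls differed along the range of signal. The median log2 change over all sites was -0.03 in the authors' deposited table, with 48.5% of sites above 0 and 51.1% below. In the lowest quartile of mean signal the median was 0.72, with 110 higher and 0 lower sites, and in the highest it was -0.36, with 196 higher and 188 lower, in the authors' deposited table. Among the 5250 sites with a summit in all 4 libraries the split turned, with 94 higher and 127 lower sites (42.5% higher, 95% interval 35.9 to 49.3%). Sites with summits in both Paupar KD libraries and no control KD library numbered 2167, of which 417 were higher and 1 lower. Those with summits in both control KD libraries and no Paupar KD library numbered 385, of which 0 were higher and 14 lower. Summits and concentrations came from the same libraries, so each of these splits by summits partly restates the calls. Summits of Paupar KD replicate 1 lay at 811 of the higher sites and summits of replicate 2 at 639. Of the 3404 sites with a summit in replicate 1 alone, 206 (6.05%) were higher. Of the 4337 sites with a summit in replicate 2 alone, 33 (0.761%) were higher. Without per-library values, no call could be refitted without a library.

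Promoters held fewer of the higher sites and more of the lower sites. They made up 28.04% of the background, 13.2% of higher sites (odds ratio 0.381, Fisher's exact test, adjusted p = 1.14e-24) and 45.0% of lower sites (odds ratio 2.12, Fisher's exact test, adjusted p = 3.19e-07). Distal intergenic sequence held 38.8% of higher sites against 28.8% of the background (odds ratio 1.60, Fisher's exact test, adjusted p = 1.05e-09), and introns 42.9% against 36.4% (odds ratio 1.33, Fisher's exact test, adjusted p = 0.000238). Introns held 26.6% of lower sites (odds ratio 0.630, Fisher's exact test, adjusted p = 0.00565). Over all 7216 promoter sites the median log2 change was -0.23, with 113 higher and 100 lower, and over the other 19028 sites it was 0.08, with 742 higher and 122 lower, in the authors' deposited table. Among sites above the median of mean signal, 46.0% of lower sites against 38.7% of sites were in promoters (Fisher's exact test, adjusted p = 0.0995), so that enrichment no longer passed.

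**Figure D3:**
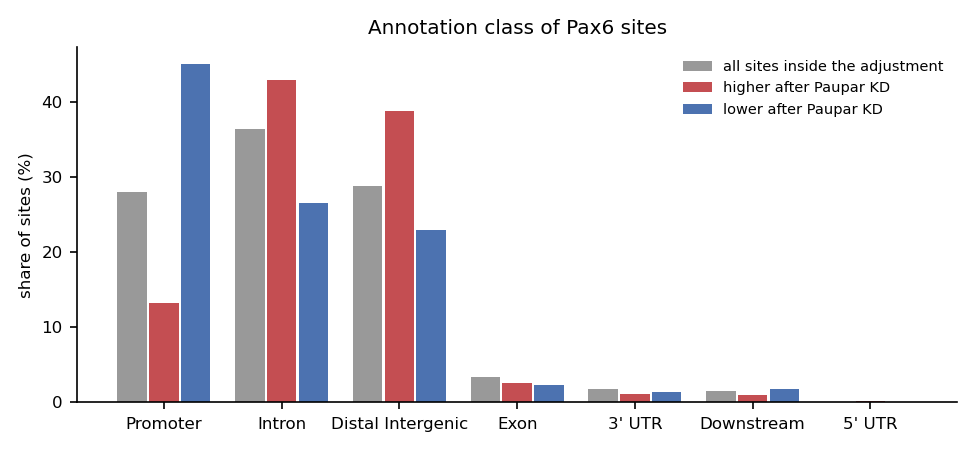
Share of sites in % (vertical axis) in each annotation class of the authors' deposited table (horizontal axis), for the 25234 background sites (grey), the higher sites (red) and the lower sites (blue). Promoters hold 28.04% of the background, 13.2% of the higher sites and 45.0% of the lower sites.

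The peak lists of single libraries were compared next. Summits numbered 14311 and 9983 in the control KD libraries and 15611 and 17942 in the Paupar KD libraries, with means of 12147 ± 3060 (SD, n = 2) and 16776.5 ± 1648 (SD, n = 2). The ratio of means was 1.38 (two-sided exact permutation p = 0.33, the smallest that 4 libraries allow). The summits formed 29164 summit sites, of which 50.8% were found in 1 library and 18.5%, or 5386, in all 4. The mean Jaccard index was 0.418 within groups and 0.370 between groups, the highest of the 3 splits of the libraries (exact permutation p = 0.33, the smallest possible); the other splits gave 0.364 and 0.375. Summit sites in both Paupar KD libraries and no control KD library numbered 2209, against 524 in both control KD libraries and no Paupar KD library, a ratio of 4.22. The other splits gave 1309 sites for control KD replicate 1 with Paupar KD replicate 2 against 255 for the remaining pair, a ratio of 5.13, and 651 against 481, a ratio of 1.35. With lists of equal length, 9983 summits each, the counts were 1067 and 809, a ratio of 1.32, while control KD replicate 1 with Paupar KD replicate 2 shared 583 such sites against 292 for the remaining pair, a ratio of 2.0.

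**Figure D4:**
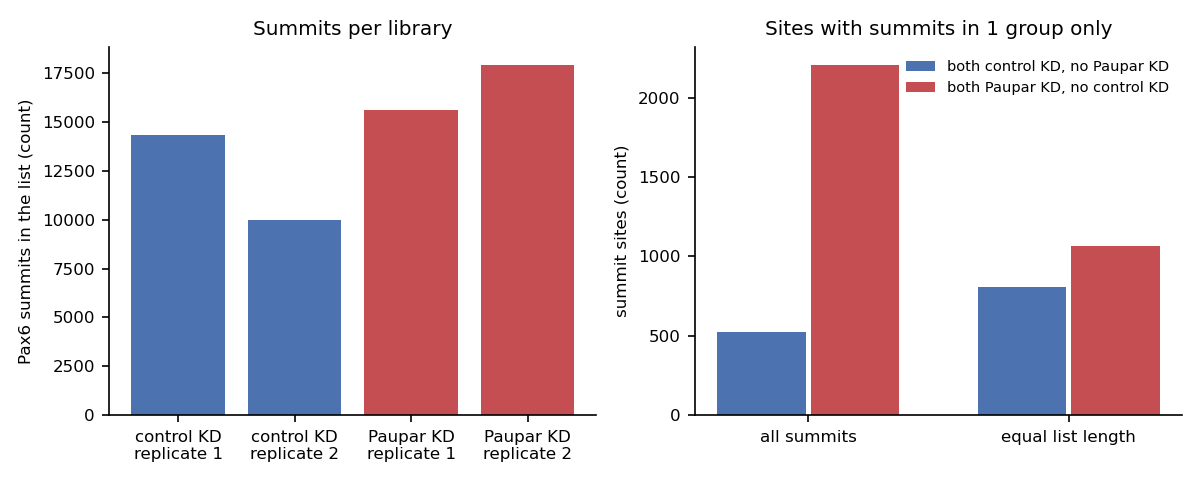
Left, the number of Pax6 summits in the list of each library; right, the number of summit sites found in both libraries of 1 group and neither of the other, with all summits and with the 9983 top-scoring summits of each list; control KD is blue and Paupar KD red, and each bar is a single count with no error. The ratio of the red to the blue bar on the right falls from 4.22 to 1.32 at equal list length.

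The Paupar-only summit sites with the highest scores lay near Barhl2, a neural homeodomain factor gene, 2210417A02Rik, Icos, Inpp5f and Abcc6. Icos, a T-cell costimulator gene, had 4.76 and 7.86 at this position (FDR 0.00547), Abcc6 5.38 and 7.48 (FDR 6.64e-08) and Inpp5f 5.65 and 7.67 (FDR 1.25e-06) in the authors' deposited table. Barhl2 had 5.74 and 6.96 (FDR 0.0128), whereas the 2210417A02Rik promoter had 6.86 and 6.87 (FDR 0.986), in the authors' deposited table. Of the 5 control-only summit sites, 1 lay at the promoter of Mbd3, a methyl-CpG binding domain gene, with 9.31 and 8.43 (FDR 0.00176) in the authors' deposited table. Others lay near Gm34068 and 2210417A02Rik, the latter with its control KD summits at 148741097 to 148741122 and its Paupar KD summits at 148741482 to 148741504 on chromosome 5. The remaining control-only summit sites, on chromosome 2 (105663294 to 105663299) and chromosome 5 (106420549 to 106420556), matched no site of the table. The former lay between Paupar, which ends at 105661343, and Pax6, which starts at 105668896. The latter lay beside the Paupar-only summits near Barhl2 (106421018 to 106421028). Both groups had summits there, which the linking distance of 250 bp parted, as at 2210417A02Rik.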

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

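Chosen after the results were seen were the adjustment over all sites, the subsets without floor sites and by summits of single libraries, the share of calls and median above the median signal (for annotation classes this subset was set before), the gene as the unit, and the summit ratio without each library and with a replicate block. The number of called sites was 1781 (1309 higher, 472 lower) at an FDR of 0.1, 402 (366 and 36) at 0.01, and 141 lower sites passed with a log2 change of at least 1 in size; stricter thresholds pass fewer sites by construction. The share of calls that were higher was 75.6% without the lowest quartile of mean signal, 53.0% in promoters, 67.3% above the median signal and 42.5%, turned to lower, at sites with a summit in all 4 libraries, which leaves out by construction higher sites without a control KD summit. The median log2 change was -0.15, -0.23, -0.26 and -0.29 in these subsets and 0.0 after centring on the median. Above the median signal 3 class tests passed in place of 5. Summit sites in all libraries made up 12.2% at a linking distance of 100 bp, 21.6% at 500 bp, 20.5% and 22.5% at scores of at least 5 and 10, 22.9% at equal list length, and 22.3 to 25.5% without each library in turn. Paupar-only sites numbered 1101 at a score of at least 10 and 1067 at equal list length; control-only sites numbered 795 at 100 bp, 267 at a score of at least 10 and 809 at equal list length, with ratios of 2.57 at 100 bp, 5.29 at 500 bp (2259 against 427) and 1.32 at equal list length. The cause of these shifts was not tested beyond list length, for which the ratio of 1.32 lay between those of the other splits, 1.13 and 2.0. The number of lists past the threshold stayed at 1 in each alternative, but the beta-cell odds ratio of 6.37 became 21.4 with the strongest site per gene (4 higher sites) and 125 in promoters (2 higher sites). Its adjusted p ranged from 0.00406 to 0.0285 over these alternatives and the sites near a summit of Paupar KD replicate 2. Of the values that could move, 69 kept their direction and, for counts, stayed within 1.5 times, for tests on their side of the threshold whatever their size, and otherwise within the spread or 95% interval; centring could not change the deposited calls. Because more higher sites had a summit of Paupar KD replicate 1, calls were counted near a summit of replicate 2 (639 higher, 183 lower); because the lists of control KD replicate 1 and Paupar KD replicate 2 were the most alike at equal length (Jaccard index 0.484), they were counted near a summit of either (640 and 210). The ratio of mean summit numbers ranged from 1.17 to 1.68 without each library. With the replicate number as a block the ratio was 1.40 (1.09 and 1.80 within the numbers; exact sign-flip p = 0.5, the smallest possible). The numbers were those of the titles, and the list of control KD replicate 2 carries another number, so this pairing is not certain. Deviations of same-numbered libraries over summit sites had a correlation of -0.008. This compares only the presence of summits, so a batch shared by same-numbered libraries cannot be excluded. The table of sites holds no value per library, so no call was refitted with a block, without a replicate, or with another test, pseudocount or library scaling. The motif alternatives were not run. Unknown read depth limits what can be said of sites at the floor.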

Other observations

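The counts of genes with several called sites and of calls per chromosome, and the tests of list length, of a single library, of weak sites, of promoters, by gene and of neighbouring sites, were chosen after the called sites were seen; for the tests by gene and of neighbouring sites the bound was set before their own values were seen. Of 753 genes with a higher site, 78 had at least 2 and 3 had at least 4: Ccdc190 (4 of 8 sites), Slc24a2, a sodium, potassium and calcium exchanger gene (4 of 14), and Foxp1, a forkhead factor gene (4 of 29). Slc24a2 also had 1 lower site (8.33 and 7.49, FDR 0.0174), as did Foxp1, at a promoter (7.56 and 6.66, FDR 0.0391), in the authors' deposited table. Snd1 had 3 higher and 3 lower of 34 sites. All 3 sites of Stk32a were higher, and so were 3 of the 4 sites of Prlr, the prolactin receptor gene. The Prlr promoter had 3.11 and 5.31 (FDR 0.0303) in the authors' deposited table. Pax3, which encodes another paired-domain factor, had 3 higher sites of 7. Pcgf5, a Polycomb ring finger gene, had 2 lower of 3 sites, with 7.03 and 5.99 at the site nearest its start (FDR 0.0253), in the authors' deposited table. Higher sites made up 3.39% of the 25234 background sites, 4.93% of those of chromosome 6 (Fisher's exact test, adjusted p = 0.00915) and 1.73% of those of chromosome 11 (adjusted p = 0.00094).

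Higher sites outnumbered lower sites, 855 to 222. A single Paupar KD library as the source cannot be told apart: of the higher sites with a summit in replicate 1 and none in control KD, 66.9% (95% interval 63.1 to 70.6%) also had one in replicate 2, against 38.9% of all such sites, but a call rests on both libraries, and the table has no value per library. By summits in 1 library alone the higher calls leaned to replicate 1, with 6.05% of 3404 sites against 0.761% of 4337 for replicate 2. Weak sites near the detection limit cannot be told apart either: above the median of mean signal 67.3% of calls were higher (95% interval 63.5 to 70.8%), but the rise itself lifts the mean. In the highest quartile 51.0% were higher (45.9 to 56.2%). Normalization that moves with signal strength, and a gain of Pax6 at weaker sites after Paupar KD, both stay open and were not tested. The longer Paupar KD peak lists, tested for summit sites alone, were not tested for these calls and stay open too.

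Promoter sites had lower log2 changes than other sites. Stronger signal at promoters as the whole source is argued against by the difference of -0.10 at matched mean signal (95% bootstrap interval -0.13 to -0.08). As part of it this stays open, since the unmatched medians were -0.23 and 0.08 and the promoter enrichment of lower sites did not pass above the median signal (Fisher's exact test, adjusted p = 0.0995). Sites missing from the control KD peak lists are argued against as well, since the difference was -0.13 (95% bootstrap interval -0.15 to -0.09) among sites with a summit in all 4 libraries. Both differences were matched on mean signal, which contains the change itself, and this limits both arguments. GC content, which was not tested, and a loss of Pax6 at promoters after Paupar KD stay open.

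Higher sites lay at alpha- and beta-cell identity genes. Counting several sites of 1 gene apart is argued against for the beta-cell list, because 5 of its 10 genes had a higher site where genes with as many sites gave 0.986 (permutation p = 0.00064); the alpha-cell list had 5 of 16 genes against 2.10 (permutation p = 0.0346, adjusted p = 0.189). A gain of a whole chromosomal region cannot be told apart: the median log2 change of 209 uncalled sites 10 kb to 1 Mb away lay 0.29 above sites of matched mean signal (95% bootstrap interval 0.04 to 0.42), which spans the 0.3 set beforehand. By distance the excess was 0.99 (-0.45 to 2.76; 4 sites) within 10 kb, 0.12 (-0.84 to 0.69) at 10 to 100 kb and 0.30 (0.04 to 0.41) at 100 kb to 1 Mb, against 0.29 (0.23 to 0.37), 0.16 (0.13 to 0.19) and 0.06 (0.03 to 0.07) around all 855 higher sites. Of the 6 higher beta-cell sites, 2 (Iapp and Npy) lay on chromosome 6, whose share of higher sites was above that of the background.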
